A study of Macaca mulatta with 12 samples.

How the data were processed

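Gene expression was measured in the dorsal raphe nucleus, the midbrain nucleus that holds most forebrain-projecting serotonin neurons, of ovariectomized female rhesus macaques. Per the labels' protocols, Silastic capsules were placed under the skin for 1 month before tissue was taken, RNA was extracted with Trizol and Qiagen columns, and biotin-labelled material was hybridized to a human Affymetrix array. The labels give 4 groups of 3 monkeys with 1 array per monkey: placebo, estrogen, progesterone, and estrogen plus progesterone. The titles of the progesterone arrays spell out progesterone alone but carry the codes EP1 to EP3, which are those of the combined group, while their source names carry P1 to P3; the group was taken from the source names. The replicates are separate animals, so the errors cover animal and array variation together.

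The deposited values are an intensity per probe set on a linear scale, for 12625 probe sets on each of the 12 arrays. From the values, every array had been scaled by the authors to a common trimmed mean of about 200.1 with 2% trimmed from each end. The method that summarised the probes, its software and its version are not given in the sources used here, and no detection calls were used. The median intensity of an array lay between 74.2 and 87.1. Probes of a human array were read with macaque RNA, so an intensity depends on sequence match as well as on transcript amount, and levels were not set against each other between probe sets. Precision is limited with 3 arrays per group.

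Probe sets were named through the platform's probe table, with symbols updated through gene identifiers. Of the probe sets other than the 67 array controls, 10943 carried 1 gene symbol, 545 carried several and 1070 carried none and are unnamed here. The single-symbol probe sets covered 8226 genes, and a probe set with several symbols was never named as a gene. The control probe sets stayed out of all tests and were used to look at ribosomal RNA signal, at spike-in controls and at the ratio of 3' to 5' signal of GAPDH and actin.

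Intensities were converted to log2(intensity + 8.26), where the offset is the pooled 10th percentile of all values. Fold changes on this scale understate the change of dim probe sets. The array medians on the log2 scale spanned 0.21, above the limit of 0.15 set for using the values as deposited, so the arrays were quantile normalized. The lowest 40% of probe sets by mean over all arrays were left out, which removed 5023 and left 7535, of which 6680 had 1 gene symbol. Group means were fitted with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes over all 12 arrays so that the 4 groups shared 1 estimate of the spread, with 2-sided tests and Benjamini-Hochberg adjustment over the tested probe sets at a threshold of 0.05. Log2 changes are given with their standard error from this fit, and intensities as deposited with the SD over 3 arrays. The comparisons were each hormone group with placebo, both hormones with each single hormone, the interaction of the 2 hormones on the log2 scale, the mean of the hormone groups with placebo, and limma's F test for any difference among the 4 groups.

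Genes were named by a fixed rule. For each comparison with placebo, these were the 10 highest and 10 lowest log2 changes among single-symbol probe sets that passed the adjusted threshold and whose 3 hormone arrays all lay outside the placebo range. Where fewer passed, the places were filled by the smallest unadjusted p under 0.01 with the same separation, and these are reported as not past the threshold. Up to 3 per direction were named for the other comparisons. All measured members of the serotonin list, the estrogen and progesterone receptors, and up to 4 members of each called gene list were added.

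Gene lists covered the serotonin, GABA, glutamate, catecholamine, acetylcholine and neuropeptide systems, the stress axis, steroid receptors with their cofactors, estrogen-responsive genes, synaptic vesicles, G-protein signalling, protein kinases A and C with CREB, ion channels, apoptosis, antioxidant enzymes, oxidative phosphorylation, glycolysis, cholesterol synthesis, immediate early genes, heat shock, the proteasome, ribosomal proteins, cytokines, growth factors and axon growth. Markers of neurons, astrocytes, oligodendrocytes, microglia, endothelium, blood, ependyma, meninges and cerebellum made up the rest of the 34 lists. Each gene entered with its probe set of highest mean, which gave 5499 genes, and a list needed 5 measured genes. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with camera at an estimated correlation and with fry.

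The comparisons with placebo share the placebo arrays. Agreement between them was therefore set against 100 simulations of unchanged groups with each probe set's own mean and spread, drawn independently of the other probe sets. The fit was tested on simulated data in which 100 probe sets were changed by each of 2 log2 sizes. A simulated log2 change of 1 was recovered for 57% of the changed probe sets with estrogen, 48% with progesterone and 50% with both hormones. A simulated change of 2 was recovered for 92%, 90% and 91%. In these simulations 12, 6 and 11 unchanged probe sets were called as well. Noise was drawn independently for each probe set. With so many changed probe sets the adjustment is milder than in the real comparisons, where 0, 3 and 1 passed. The percentages therefore do not give the power of the real comparisons, which is lower. A simulated shift of 0.3 of the synaptic vesicle list with progesterone gave an adjusted p of 0.00395.

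The groups, the comparisons, the offset, the normalization rule, the filter, the naming rule, the gene lists and the main alternatives were chosen before the data were examined. The alternatives were the values as deposited, a shift of arrays to a common median, no filter, a filter that dropped the lowest 60%, offsets of 1 and of the 25th percentile (23.8), a variance trend with robust fitting, array weights, the replicate number as a block, fits of only the groups compared, and each array left out in turn. For the lists, the mean of a gene's probe sets, the estimated correlation and fry were added to these. A fit without estrogen array 1 and estrogen plus progesterone array 1, averages of each hormone over the presence of the other, and, for the estrogen and estrogen plus progesterone arrays, a paired fit and a simulation with same-numbered arrays varying together were added after the data were seen. Same-numbered arrays of these 2 groups deviated together from their group means, with correlations of 0.407, 0.296 and 0.133. That comes from the values, as no label ties the animals or arrays by number, and both arrays of high ribosomal signal carry number 1. In no other 2 groups did all 3 same-numbered pairs exceed 0.1. Deviations from a group mean cancel out within the group. A deviation shared by the 2 arrays of number 1 alone thus also raises the correlations of the other pairs. The 3 correlations are therefore not 3 separate signs of pairing. Regroupings of the arrays were counted in full where there were 10 and otherwise limited to 100 drawn with a fixed seed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.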

Results

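Transcript intensities were compared in the dorsal raphe nucleus of 12 ovariectomized rhesus macaques that had carried placebo, estrogen, progesterone or combined implants for 1 month, with 3 monkeys per treatment. The design asks how each ovarian steroid, alone and together, changed gene expression in this serotonin-producing nucleus. Of 12625 probe sets, 7535 were bright enough to be tested. Spearman correlations between arrays lay between 0.911 and 0.967 across probe sets, which are not independent replicates.

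Estrogen array 1 and estrogen plus progesterone array 1 stood apart from the other 10 arrays. The 28S ribosomal RNA control read 841 on the first and 1354 on the second, against at most 179 on the others. The 3' part of the 18S control read 439 and 486 on these arrays and at most 116 elsewhere. The ratio of 3' to 5' GAPDH signal was 2.45 and 2.05, against at most 1.46. Principal component 1, which held 22.9% of the variance, placed them at 39.1 and 28.6, while the others lay between −13.6 and −1.30. On component 2, which held 15.0% of the variance, placebo array 1 lay at −33.8. Progesterone arrays 1, 2 and 3 lay there at 18.2, 9.16 and 15.9, above every other array (highest 5.41, estrogen array 1). Both arrays with high ribosomal signal came from estrogen-treated monkeys, so each mean with estrogen and each mean with both hormones includes 1 of them.

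**Figure D1:**
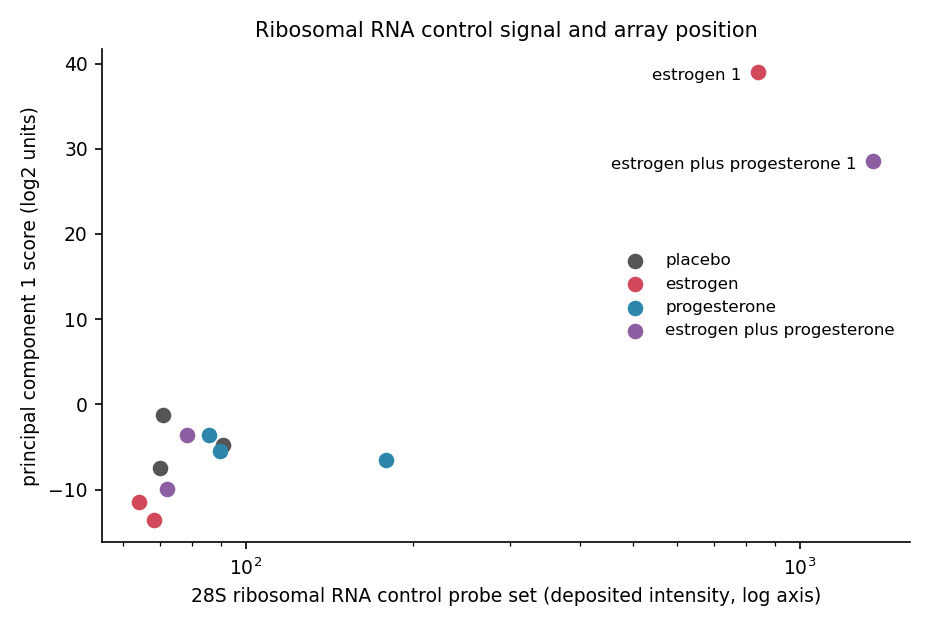
Each point is 1 of the 12 arrays, coloured by treatment, with the deposited intensity of the 28S ribosomal RNA control on a log axis against the score on principal component 1 in log2 units. Estrogen array 1 (841, 39.1) and estrogen plus progesterone array 1 (1354, 28.6) lie away from the other 10 arrays, whose scores lie between −13.6 and −1.30.

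With estrogen alone, the clearest separation from placebo was in ADGRE5, the leukocyte adhesion receptor also called CD97. Its intensity was 29.1 ± 5.9 (SD, n = 3) with placebo and 79.2 ± 12.9 with estrogen, a log2 change of 1.16 ± 0.20 (SE) that did not pass the threshold (limma adjusted p = 0.571). The other values on the higher side were 1.40 for DMAC2L, 1.05 for the S-phase cyclin CCNA2, 0.81 for NIPSNAP1, 1.09 for ASIP, 1.11 for TCP10L3, 0.76 for the interferon-induced IFIT1, 0.81 for the neuronal transcription factor NEUROD2, 1.28 for the DNA repair enzyme MGMT and 0.83 for STARD8. On the lower side they were −0.76 for COL11A2, −0.63 for TWF1, −0.89 for RABL3, −1.19 for MYOD1, −1.12 for the potassium-chloride cotransporter SLC12A4, −0.76 for the chaperonin subunit CCT4, −0.80 for growth hormone releasing hormone (GHRH), −0.74 for ARMCX6, −0.74 for the prion protein PRNP and −0.64 for CHST3. Second probe sets of CCNA2, IFIT1 and MGMT gave 0.08, 0.16 and −0.25. The other probe sets of COL11A2 gave −1.24 and −0.32, those of DMAC2L −0.27 and −0.055, and those of SLC12A4 0.0058 and −0.12.

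No probe set passed limma's adjusted threshold for estrogen against placebo. At an unadjusted p under 0.05 there were 238 probe sets, 122 higher and 116 lower, where 376.75 would be counted with no effect. The estrogen and placebo arrays did not overlap for 462 probe sets (6.13%), against the 10% that chance gives for 3 against 3. The count at the adjusted threshold was also 0 in each alternative fit. The 238 became 385 without both arrays of high ribosomal signal and 390 with array weights, both above 376.75.

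With progesterone alone, 3 genes passed the threshold. UBXN7, an adaptor of the p97 segregase, rose from 34.8 ± 12.9 to 119 ± 17.1 (SD, n = 3), a log2 change of 1.61 ± 0.21 (SE, limma adjusted p = 0.0305). PRRC2C, which encodes a large proline-rich coiled-coil protein, rose from 86.4 ± 28.7 to 243 ± 16.8, by 1.46 ± 0.21 (adjusted p = 0.0451). LPCAT4, an acyltransferase that remodels membrane phospholipids, went from 121 ± 31.1 to 19.1 ± 2.9 and fell by 2.24 ± 0.28 on the log2 scale (adjusted p = 0.0305). For these probe sets all 3 progesterone arrays lay outside the range of the 3 placebo arrays. A second PRRC2C probe set gave 0.03.

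Further genes with separated arrays did not pass. On the higher side these were DMAC2L at 1.68 (limma adjusted p = 0.0685), the angiogenic factor AGGF1 at 1.02 (0.0972), the limbic adhesion protein LSAMP at 1.11 (0.141), NKTR at 1.30, the kinase CDC42BPA at 1.76, the tyrosine phosphatases PTPN1 at 0.84 and PTPN4 at 1.54, and the bicarbonate cotransporter SLC4A7 at 1.61. Other probe sets gave 1.55 for PTPN4, 0.32 and 1.39 for NKTR, 1.39 and −0.33 for PTPN1, −0.15 and −0.12 for DMAC2L, and −0.31 for CDC42BPA on a brighter probe set. On the lower side the RNA helicase DDX17 read 2081 ± 112 with placebo and 1121 ± 92.5 with progesterone, −0.91 ± 0.15 (adjusted p = 0.0789), while its second probe set gave 0.0078. The glial transcription factor SOX9 read 297 ± 13.7 and 165 ± 26.9, −0.80 ± 0.16 (adjusted p = 0.177). Other values were −0.80 for the neural transcription factor POU3F2, −0.94 for RANBP9, −1.41 for LOC391322, −1.12 for NTRK2, the BDNF receptor, −0.81 for RAPGEF2 and −0.84 for APPBP2, and RANBP9 gave 1.30 on another probe set. Further probe sets of NTRK2 gave 0.61, 0.63 and −0.50, that of RAPGEF2 −0.26 and that of APPBP2 −0.11. One probe set of the chaperone gene HSPA2 read 97.5 to 202 on the placebo arrays and 2.6 to 3.8 on the progesterone arrays, under the offset of 8.26, so the offset sets the size of its difference and no log2 value is given (adjusted p = 0.174). That probe set also read 4.7 on estrogen array 2, under the offset, against 105 and 134 on estrogen arrays 1 and 3. A second HSPA2 probe set gave −0.93 with progesterone.

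With the 3 called probe sets included, 621 had an unadjusted p under 0.05 (295 higher and 326 lower, against 376.75 with no effect), and 1255 (16.7%) did not overlap between the groups, against 10% by chance. The count of 3 went to 0 when placebo 1, placebo 2, progesterone 1, progesterone 2 or progesterone 3 was left out, and in a fit of only the 6 arrays compared. For LPCAT4 the adjusted p was then 0.0782, 0.0703, 0.10, 0.0880, 0.121 and 0.0851 in that order, in a range of 0.0034 to 0.121 over its 16 alternatives. PRRC2C lost its call without any 1 of placebo 1 (0.0782), 2 (0.0703) or 3 (0.0685) or progesterone 1 (0.10), 2 (0.242) or 3 (0.209), with the values as deposited (0.0940), with no filter (0.0522), with variance trend and robust fitting (0.0545) and in the fit of only 6 arrays (0.148), in a range of 0.0176 to 0.242 over 17 alternatives. UBXN7 lost it without placebo 1 (0.0782) or 2 (0.0748), as deposited (0.0702), with variance trend and robust fitting (0.0930) and with only 6 arrays (0.144), in a range of 0.0117 to 0.144 over 13 alternatives, and it fell under the filter when a progesterone array was left out.

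**Figure D2:**
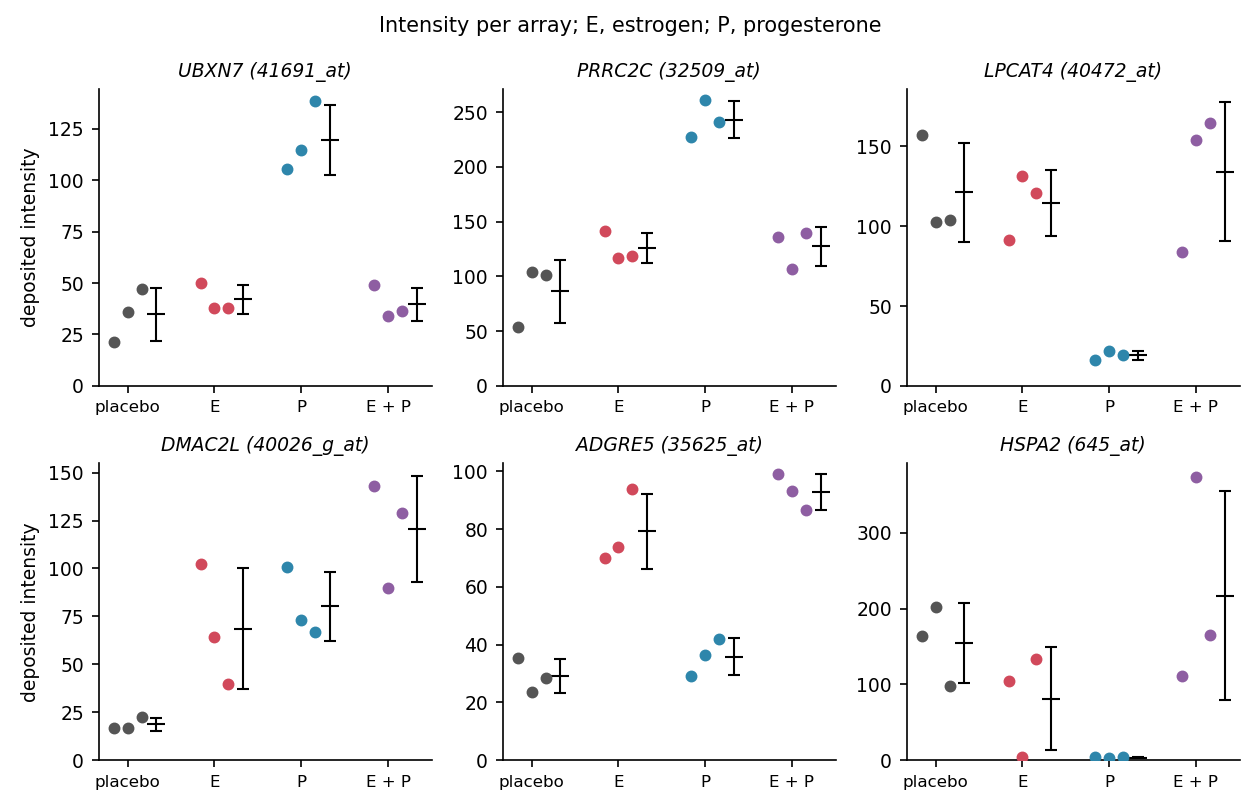
Deposited intensity of 6 probe sets on each array (points), with the mean and SD of 3 arrays per group (black bars), each titled with its gene and probe set; E stands for estrogen and P for progesterone. UBXN7 and PRRC2C are higher and LPCAT4 is lower on the progesterone arrays, DMAC2L is lowest with placebo, and ADGRE5 is higher on the arrays with estrogen. HSPA2 lies between 2.6 and 3.8 on the progesterone arrays and at 4.7 on estrogen array 2.

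With both hormones, DMAC2L, which encodes a factor associated with mitochondrial ATP synthase, rose. One of its 3 probe sets went from 18.7 ± 3.4 to 121 ± 27.7 (SD, n = 3), a log2 change of 2.18 ± 0.26 (SE, limma adjusted p = 0.0212), with all 3 arrays above all 3 placebo arrays. The other probe sets of the gene gave −0.04 and 0.25. ADGRE5 read 92.8 ± 6.1, a change of 1.37 ± 0.20 that did not pass (adjusted p = 0.0617). Prodynorphin (PDYN), the precursor of the dynorphin opioid peptides, read 91.4 ± 34.3 with placebo and 22.9 ± 1.9 with both hormones, −1.66 ± 0.34 (adjusted p = 0.456).

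Other values with both hormones that did not pass were 0.94 for the protocadherin PCDH1, 1.09 for ASIP, 0.76 for the replication factor RFC4, 1.67 for the mitochondrial enzyme ALDH6A1, 0.74 for NIPSNAP1, 1.49 for the cell cycle transcription factor E2F1, 0.58 for POFUT2 and 1.51 for SECTM1. On the lower side they were −1.07 for SRPX, −1.42 for the mitochondrial carboxylase subunit PCCA, −1.18 for the ubiquitin ligase subunit BTRC, −0.97 for PRNP, −0.89 for the B-cell receptor component CD79A, −1.54 for LYZL6, −0.58 for the growth regulator TSC2, −0.64 for the purine enzyme ADSL and −0.72 for MAP4K5. Further probe sets gave −0.081 for PCDH1, 0.16 for RFC4, −0.065 for E2F1, 0.47 and −0.62 for BTRC and 0.44 for LYZL6. With DMAC2L included, 255 probe sets had an unadjusted p under 0.05 (136 higher and 119 lower), fewer than the 376.75 counted with no effect but 454 with array weights, and 672 (8.92%, chance 10%) did not overlap. The DMAC2L call was lost without placebo 1 (adjusted p = 0.0957), placebo 2 (0.187), placebo 3 (0.0806), estrogen plus progesterone 1 (0.178) or estrogen plus progesterone 3 (0.10), in a range of 0.0043 to 0.187 over 16 alternatives. It was also lost without the filter (0.0587), in a fit of only the groups compared (0.0801), and without both arrays of high ribosomal signal (0.0662).

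Adding progesterone to estrogen gave values of 1.04 for the splicing factor PLRG1, 2.05 for the G-protein subunit GNB2 and 0.78 for FSCN2, and of −1.07 for HOXB3, −1.41 for PDYN and −0.75 for ADSL. PDYN read 75.7 ± 19.0 with estrogen and 22.9 ± 1.9 with both hormones (SD, n = 3). None of these passed: limma called 0 probe sets for this comparison, with 216 at an unadjusted p under 0.05 and 508 (6.74%, chance 10%) that did not overlap. The 216 became 477 without estrogen array 1, which had high ribosomal signal, 342 without both such arrays, 541 with array weights, and 347 in a fit of these 6 arrays with same-numbered arrays paired, which also called 0. Without estrogen array 2 the count was 2, and GNB2 then had a change of 2.81 (adjusted p = 0.0178). A second GNB2 probe set gave −0.040 over all arrays.

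LPCAT4 was higher with both hormones than with progesterone alone. It read 19.1 ± 2.9 with progesterone and 134 ± 43.7 with both hormones (SD, n = 3), a log2 change of 2.31 ± 0.28 (SE, limma adjusted p = 0.0259). LPCAT4 also read 103 to 157 on the placebo arrays and 91.4 to 131 on the estrogen arrays. Its call against placebo, this call and its interaction value thus rest on the same 3 low progesterone readings. DDX17 at 0.95 (0.0896), ADGRE5 at 1.19 (0.0944), UBXN7 at −1.46 (0.0790), BTRC at −1.42 (0.0944) and CDC42BPA at −1.91 (0.127) did not pass. Other probe sets gave −0.17 for DDX17, 1.06 and −0.079 for BTRC and 0.28 for CDC42BPA. At an unadjusted p under 0.05 there were 581 probe sets, and 1186 (15.7%, chance 10%) did not overlap. The LPCAT4 call was lost without estrogen plus progesterone 2 (adjusted p = 0.230) or 3 (0.103), and without progesterone 1 (0.102), 2 (0.128) or 3 (0.0886), in a range of 0.0005 to 0.230 over 16 alternatives. It was also lost with the larger offset (0.0592) and in a fit of only the groups compared (0.0737).

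Whether the hormones added up was tested by their interaction. For LPCAT4 it was 2.40, for POU3F2 1.07, for UBXN7 −1.71, for PRRC2C −1.46 and for CCNA2 −1.62, none past the threshold (limma adjusted p = 0.439 for LPCAT4 and UBXN7 and 0.585 for the others). Second probe sets of PRRC2C and CCNA2 gave −0.079 and −0.25. For HSPA2 the readings under the offset, on the progesterone arrays and on estrogen array 2, leave the size open, and its second probe set gave 1.43. The interaction count was 0, with 376 probe sets at an unadjusted p under 0.05 and 376.75 with no effect, and was 1 without placebo array 3.

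Against the mean of all hormone groups, DMAC2L rose by 1.75 ± 0.21 (SE, limma adjusted p = 0.0250) over 9 hormone and 3 placebo arrays, higher on 9 of 9. ASIP at 1.09 (0.519), NIPSNAP1 at 0.74, PRNP at −0.80, MAP4K5 at −0.69 and POU3F2 at −0.52 did not pass. The other DMAC2L probe sets gave −0.15 and 0.025. There were 321 probe sets at an unadjusted p under 0.05, 198 without placebo 1, and 34 (0.451%, chance 0.909%) did not overlap. The DMAC2L call was lost without placebo 1 (0.356), 2 (0.317) or 3 (0.0773), estrogen 2 (0.0829), estrogen plus progesterone 1 (0.0666) or 3 (0.0834), or progesterone 1 (0.0649), 2 (0.0737) or 3 (0.0512), with no filter (0.0688), with the larger offset (0.0589), with variance trend and robust fitting (0.0566) and without both arrays of high ribosomal signal (0.0506), in a range of 0.0088 to 0.356 over 21 alternatives.

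Over the 4 groups together, limma's F test called ADGRE5, DMAC2L, LPCAT4 and UBXN7, each with an adjusted p of 0.0481, and 436 probe sets had an unadjusted p under 0.05. ADGRE5 read 29.1 ± 5.9 with placebo, 35.8 ± 6.3 with progesterone, 79.2 ± 12.9 with estrogen and 92.8 ± 6.1 with both (SD, n = 3). Leaving out 1 array gave between 0 and 4 calls. The count was 0 with arrays shifted to a common median, with the lowest 60% left out and with the larger offset.

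None of the 21 measured genes of the serotonin system passed the threshold in a comparison with placebo. The serotonin transporter SLC6A4 read 434 ± 39.9 with placebo, 376 ± 13.6 with estrogen, 282 ± 21.6 with progesterone and 390 ± 149 with both hormones (SD, n = 3), and its change with progesterone was −0.58 ± 0.26 (SE, limma adjusted p = 0.585). The receptor HTR2C read 362 ± 38.0 and 229 ± 24.3 with placebo and progesterone, −0.62 ± 0.18 (adjusted p = 0.393), and the transcription factors GATA3 and LMX1B, which help specify serotonin neurons, gave −0.62 and −1.01 there. MAOA, which degrades serotonin, read 326 ± 99.2 with placebo and 587 ± 200 with estrogen, 0.80 ± 0.26, and its change was 0.49 with progesterone and 0.10 with both. A dimmer MAOA probe set gave −0.068, −0.70 and −0.28 with estrogen, progesterone and both, so the 2 tested probe sets of the gene did not agree, and the remaining one was too dim to be tested. FEV, the serotonin neuron transcription factor, gave 0.43, 0.02 and 0.02 with estrogen, progesterone and both. TPH1 was too dim to be tested, and no probe set was named TPH2.

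As a group the serotonin genes had a median change of 0.010 with estrogen (12 higher and 9 lower), −0.11 with progesterone (7 higher and 14 lower) and −0.016 with both (10 higher and 11 lower). Camera's adjusted p was 0.955, 0.627 and 0.856. In each comparison 0 members passed over all probe sets and 0 passed when adjusted over the list alone, by limma.

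**Figure D3:**
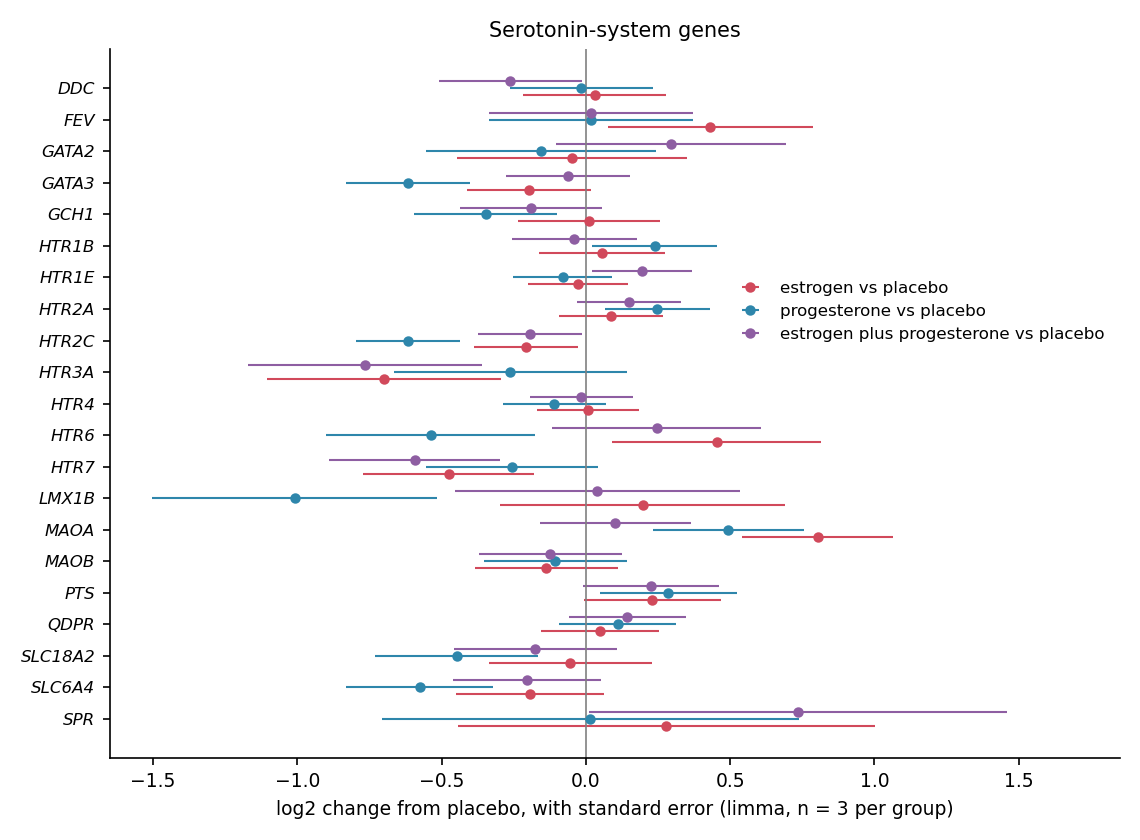
Log2 change from placebo (points) with its standard error (bars, limma, n = 3 per group) for the 21 measured serotonin-system genes under estrogen, progesterone and both hormones. MAOA with estrogen lies at 0.80, and HTR2C, GATA3 and SLC6A4 with progesterone lie at −0.62, −0.62 and −0.58; none passed the adjusted threshold.

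No probe set of the estrogen receptors passed the threshold. The bright probe set of ESR2 read 201 ± 19.0 with placebo, 217 ± 62.3 with estrogen, 211 ± 6.1 with progesterone and 220 ± 21.1 with both hormones (SD, n = 3). Its dimmer tested probe set gave log2 changes of 0.37, 0.60 and 0.29 with estrogen, progesterone and both. The brighter tested probe set of ESR1 read 226 ± 127, 274 ± 109, 304 ± 26.9 and 253 ± 49.0 in the order of the groups above (changes of 0.41, 0.63 and 0.33), and the other read 189 ± 29.0, 185 ± 80.9, 213 ± 26.7 and 189 ± 51.8 (−0.097, 0.17 and −0.037). An ESR1 probe set below the filter gave −0.68, −0.92 and −0.36. Of the 4 probe sets named for each, 2 were bright enough to be tested, and the lowest limma adjusted p over all of them without the filter was 0.727. The progesterone receptor probe set (PGR) read 4.1 ± 5.6 with placebo, 2.5 ± 1.8 with estrogen, 5.2 ± 2.6 with progesterone and 3.1 ± 3.2 with both, below the filter and below the offset of 8.26, so no change of PGR was detectable here.

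Of the 34 gene lists, camera called 1, the markers of cerebellum with estrogen. All 8 measured members were higher, with a median of 0.25 (camera adjusted p = 0.0441; adjusted p = 0.920 with an estimated correlation). ZIC1, a cerebellar granule cell transcription factor, gave 1.10 ± 0.45 (SE), the calcium binding protein CALB1 0.43, the calcium channel ITPR1 0.33 and PCP4 0.23, and none of the 8 passed by itself. ZIC1 read 252 ± 185 with estrogen and 93.9 ± 10.7 with placebo, with 462 on estrogen array 2, where the list's score was 0.75 against 0.46 on estrogen plus progesterone array 2 and at most 0.19 on the other arrays. The call was lost without estrogen 2 (median 0.11, adjusted p = 0.976), placebo 1 (0.0776), placebo 2 (0.102), placebo 3 (0.216), estrogen plus progesterone 1 (0.0609) or progesterone 1 (0.0516), and without both arrays of high ribosomal signal (0.0536). It was also lost with the mean of a gene's probe sets (0.0555) and by fry's directional test (0.807). ITPR1, PVALB and CALB1 are also expressed in other brain regions, and SLC1A6 and GRM4 also belong to the glutamate list.

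With estrogen the oligodendrocyte and myelin markers had a median of −0.16, with 2 higher and 13 lower, and did not pass (camera adjusted p = 0.216; adjusted p = 0.972 with an estimated correlation). Without estrogen array 1, the array with high ribosomal signal, the median was −0.24 and the camera adjusted p 0.0275. Without estrogen array 2 they were −0.070 and 0.976. The list's score was 0.038, −0.350 and −0.115 on estrogen arrays 1, 2 and 3, so the lower values rested largely on array 2. With progesterone the astrocyte markers had a median of −0.15, 7 higher and 10 lower, and did not pass camera (adjusted p = 0.378). Fry's test for change in either direction called this list alone (adjusted p = 0.0098). At an unadjusted p under 0.05, 5 members were lower and 0 higher: SOX9 at −0.80, the bicarbonate cotransporter SLC4A4 at −0.67, FGFR3 at −0.52, the glutamine synthetase GLUL at −0.45 and GFAP at −0.42. The glutamate transporter SLC1A2, at 1.16 ± 0.76 (SE), was not among them.

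Adjusted over the list alone, 4 genes passed that did not pass over all probe sets, in 4 of the 102 combinations of list and comparison, where 5.1 would hold a call with no effect. With progesterone these were SOX9 (0.0053 in the astrocyte list) and the GABA receptor subunit GABRB2 (0.0215 in the GABA list), which read 104 ± 15.5 with placebo and 214 ± 16.8 with progesterone, 1.002 ± 0.24 (SE, n = 3, limma adjusted p = 0.313 over all). With both hormones they were PDYN (0.0087 in the neuropeptide list) and CD79A (0.0113 in the blood cell list).

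The other transmitter lists did not pass, and their medians are given in the order estrogen, progesterone and both hormones. They were 0.15, −0.036 and 0.094 for 14 GABA genes, 0.087, −0.016 and 0.048 for 22 glutamate genes, 0.052, −0.096 and 0.018 for 11 catecholamine genes, and −0.16, −0.098 and 0.016 for 6 acetylcholine genes. The 24 neuropeptide genes gave −0.084, −0.21 and 0.0013, and the 25 synaptic vesicle genes gave 0.029, −0.17 and −0.024. For hormone signalling they were −0.029, −0.093 and −0.0057 for 17 steroid receptors and cofactors, −0.070, −0.13 and −0.059 for 19 estrogen-responsive genes, and −0.021, −0.079 and −0.033 for 13 stress axis genes.

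Signalling and channel lists gave, in the same order, 0.052, 0.0083 and 0.053 for 32 G-protein genes, −0.043, 0.029 and 0.041 for 21 kinase A and C and CREB genes, 0.040, −0.048 and 0.040 for 29 ion channel genes, −0.021, 0.0080 and −0.024 for 27 growth factor genes, and 0.061, −0.0072 and 0.033 for 30 axon growth genes. Stress and survival lists gave 0.010, 0.14 and 0.018 for 24 apoptosis genes, −0.077, 0.091 and −0.042 for 17 antioxidant genes, −0.090, 0.032 and 0.0028 for 28 heat shock genes, 0.044, −0.010 and −0.13 for 21 immediate early genes, and 0.059, 0.099 and 0.072 for 22 cytokine genes. Metabolic and housekeeping lists gave 0.010, 0.013 and 0.011 for 48 oxidative phosphorylation genes, 0.025, 0.061 and 0.029 for 17 glycolysis genes, 0.087, −0.0018 and 0.085 for 17 cholesterol genes, 0.062, 0.077 and 0.0045 for 32 proteasome genes, and 0.0032, 0.012 and 0.074 for 46 ribosomal protein genes.

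Among cell markers the medians were 0.11, 0.052 and 0.032 for 17 neuronal genes, −0.10, 0.14 and −0.14 for 14 microglial genes, −0.20, 0.046 and 0.20 for 11 endothelial genes, −0.0052, 0.062 and 0.061 for 7 blood cell genes, −0.19, 0.15 and 0.023 for 6 ependymal genes, and −0.037, −0.11 and 0.030 for 8 meningeal genes. The astrocyte markers gave 0.025 with estrogen and −0.065 with both, the myelin markers −0.035 with progesterone and −0.057 with both, and the cerebellar markers 0.032 and 0.15. For some lists the sign of the median, the mean and the test was not the same: 9 of 34 with estrogen, 9 with progesterone, 7 with both hormones and 6 for the mean of all hormone groups. Among these were the GABA and glutamate lists with progesterone and the astrocyte list with both. With progesterone, camera called 0 lists (2 at an unadjusted p under 0.05, 0 by fry's directional test), with both hormones 0 (1 and 0), and for the mean of all hormone groups 0 (2 and 0). Leaving out placebo 1 called the proteasome list with estrogen and with progesterone and the ribosomal protein list with both, and leaving out progesterone 1 called the synaptic vesicle, proteasome and ribosomal protein lists with progesterone, 3 in all. These calls rest on the preset correlation of 0.01, whereas the correlations estimated over all arrays were 0.194, 0.093 and 0.335 for these 3 lists, and with estimated correlations over all arrays camera called 0 lists.

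**Figure D4:**
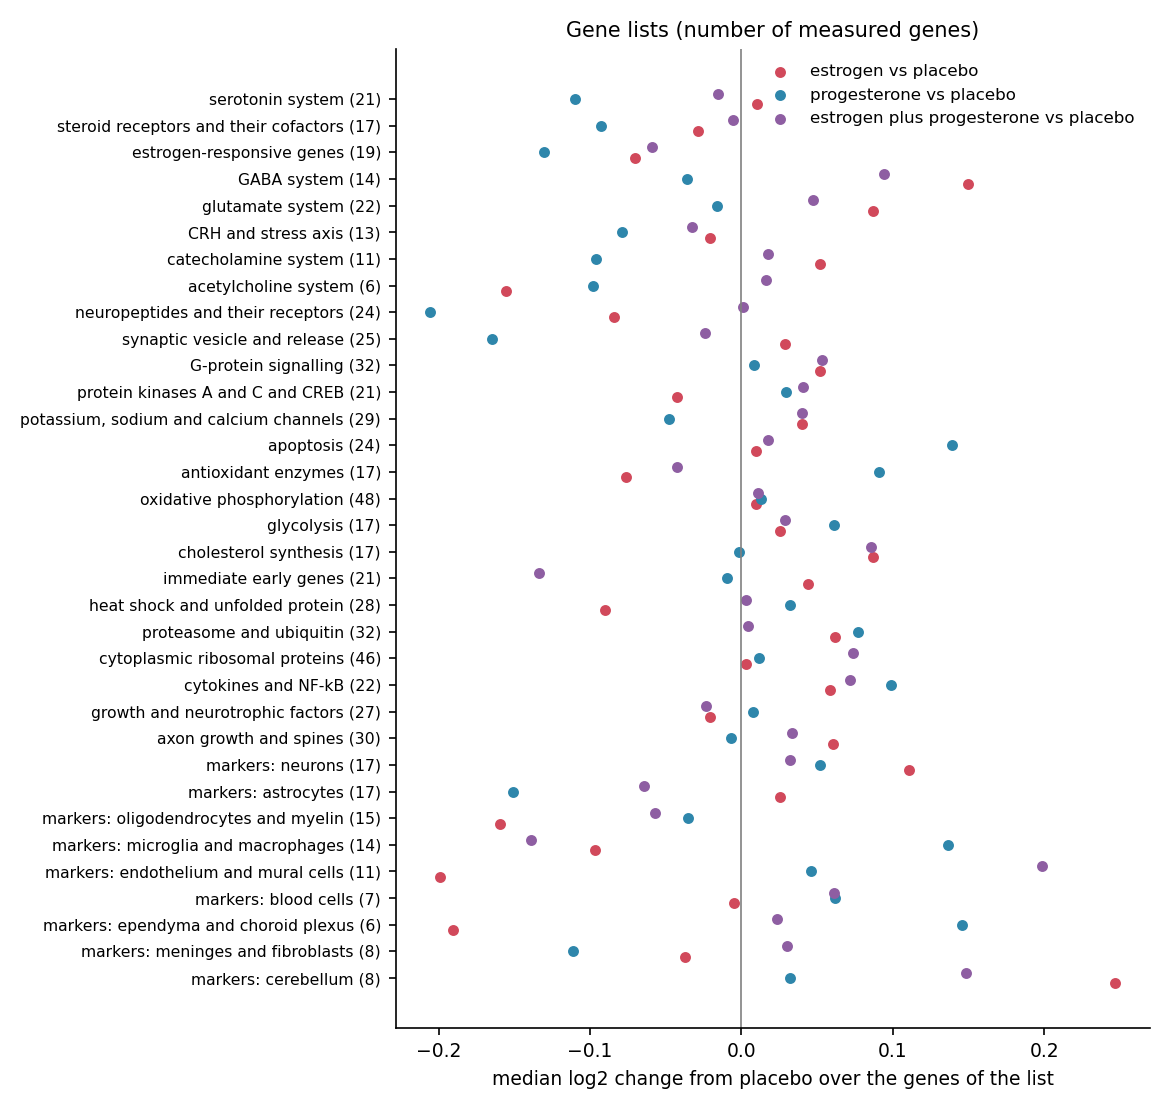
Median log2 change from placebo over the measured genes of each of 34 lists (number in brackets), with 1 point for estrogen, 1 for progesterone and 1 for both hormones. The medians lie between −0.21 and 0.25, and the cerebellum markers with estrogen (0.25) were the 1 list called by camera.

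Likeness between the comparisons with placebo was set against what shared placebo arrays produce. Across probe sets the correlation was 0.424 between estrogen and progesterone, 0.541 between estrogen and both hormones, and 0.407 between progesterone and both, where unchanged groups simulated against the same placebo arrays gave 0.500, 0.500 and 0.499. The correlation of estrogen with both hormones lay above the highest of 100 simulations (0.527) and the others lay below the simulated mean. The simulations drew each probe set independently, and their SDs were 0.015, 0.013 and 0.012. On the real arrays probe sets varied together, with 22.9% of the variance on component 1. The other correlations also lay far outside the simulated spread, so a place above all simulations does not exclude chance. Without the filter the correlation of estrogen with both hormones was 0.511, under the highest simulated value of 0.535. Unchanged groups whose same-numbered estrogen arrays vary together, at the mean correlation of 0.278 seen between them, gave 0.640 on average, so covariation of that size gives more than 0.541 with no hormone effect. That simulation gave all 3 pairs the same covariation, whereas in the data the arrays of number 1 may carry part of it. The covariance minus its simulated value was −0.0057, −0.0034 and −0.0066. Among probe sets at an unadjusted p under 0.05 in both comparisons, 36, 38 and 39 were higher in both and 15, 18 and 25 lower in both, against 4.78, 2.20 and 5.32 and 5.02, 1.83 and 5.15 for independent lists. Simulated unchanged groups gave 89.4, 89.9 and 89.9 probe sets in the same direction, and 51, 56 and 64 were observed. The 3 placebo arrays cannot be divided so that each part keeps 2 arrays. In the simulations shared placebo arrays alone gave more probe sets in the same direction than were observed. These counts were not matched for list size. The real lists held 238 with estrogen, 621 with progesterone and 255 with both, where 376.75 are counted with no effect. Shared placebo arrays alone can thus give an excess over independent lists, so that excess is no sign of a shared hormone effect.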

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

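The tests of the 2 arrays that stood apart, of the progesterone count and of DMAC2L, and the regroupings by same-numbered pairs, for the unadjusted progesterone count, for the mean of all hormone groups and for the hormone averages, were chosen after the results were seen; the regroupings for the other comparisons were planned.

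Ribosomal RNA controls, which enter no comparison, exceeded the mean of the placebo arrays by more than 3 SD on 3 arrays. The 3' part of the 18S control read 439 on estrogen array 1 and 486 on estrogen plus progesterone array 1, where the placebo arrays read 49.0 to 92.1 and the limit was 136. The middle part of the 28S control read 841 on estrogen array 1, 1354 on estrogen plus progesterone array 1 and 179 on progesterone array 3, where the placebo arrays read 70.0 to 90.8 and the limit was 112.

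Estrogen array 1 and estrogen plus progesterone array 1 lay apart from the other 10 arrays on principal component 1. A difference in the distributions of the arrays is argued against. The gap to the nearest other array was 30.6 with the values as deposited. It was 29.9 after quantile normalization, which made the distributions of the arrays alike. What the authors' scaling did to weak signal was not tested, as both sets of values carry it. The 2nd percentile of intensity was 4.16 and 3.62 on these arrays, against at most 2.84 on the others. Estrogen treatment itself is argued against, since 0 of the 4 other arrays of estrogen-treated monkeys lay above every array without estrogen. More ribosomal RNA in the labelled material may be the source, as the lower 28S signal of these arrays was 4.70 times the highest of the others. The spike-in controls, which are not monkey RNA, were higher there too. CreX read 18865 and 20973, against at most 12142 on the others, and BioDn read 9355 and 9130, against at most 4987. The high readings were thus not limited to ribosomal RNA, which stays open as the source. Whether the difference came from the tissue piece, the RNA or the labelling stays open as well.

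Progesterone gave 621 probe sets at an unadjusted p under 0.05 where 376.75 are counted with no effect. The quantile normalization is argued against as the source by 613 such probe sets with the values as deposited. The scaling by the authors, which those values carry, was not tested. The arrays of high ribosomal signal are argued against by 708 in a fit that holds only placebo and progesterone arrays. A batch of the progesterone arrays could not be tested, because 0 labels name a batch, so batch and hormone cannot be told apart. The 10 regroupings of these 6 arrays are too few for a share under 0.05, and the highest other count was 569, with placebo 1 beside progesterone 2 and 3, which points to a structure of the arrays. The ratio of 3' to 5' actin signal was 1.54 on placebo 1, 1.73 on progesterone 2 and 1.75 on progesterone 3, and 1.03 on progesterone 1. It was also 1.69 on estrogen 3 and at most 1.34 elsewhere, and its part in that structure was not tested. Progesterone treatment and that structure both stay open as sources.

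The called DMAC2L probe set was higher with both hormones by 2.18. Its change was 2.24 with the values as deposited, which argues against the quantile normalization as its source. The scaling by the authors, which the deposited values carry, was not tested. A like change of all transcripts of the gene is argued against by its other probe sets, of which the highest gave 0.25. A change limited to the sequence that this probe set reads, or cross-hybridization to another transcript, may be the source and stays open.

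Regroupings of the arrays were counted for each comparison. With 10 regroupings a share under 0.05 cannot be had; the real count and the highest other were 0 and 1 for estrogen, 3 and 1 for progesterone, 1 and 1 for both hormones, 0 and 5 for both hormones against estrogen, and 1 and 0 for both against progesterone. The count of 5 put estrogen 1, estrogen plus progesterone 1 and estrogen plus progesterone 3 together, which points to a structure of the arrays. That regrouping keeps the 2 arrays of number 1 together, while the 4 that part all 3 same-numbered pairs, the real one included, gave 0 (highest other 0), and the 6 that part 1 pair gave up to 5. Chance was not excluded for the mean of all hormone groups, where 16 of 100 regroupings gave at least the real count of 1 and the highest other was 9, from the 3 progesterone arrays set against the rest, which points to a structure of the samples along progesterone. For the F test 8 of 100 gave at least 4 (highest other 4), so chance was not excluded there either. For the interaction the real count of 0 is reached by 100 of 100 regroupings of necessity (highest other 2), which tests nothing. For the gene lists the real count and the highest other were 1 and 2 for estrogen, 0 and 9 for progesterone and 0 and 1 for both hormones, with too few regroupings for a share under 0.05, and 0 and 12 for the mean of all hormone groups, where a real count of 0 leaves nothing to test. The counts of 9 and 12 lists both put placebo 1 beside progesterone 2 and 3, a structure of the arrays.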

How the results depend on the processing

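The fit without estrogen 1 and estrogen plus progesterone 1 and the blocked fit of 6 arrays were chosen after seeing the data; the other alternatives were planned. No gene named by size or p changed sign in 1392 alternative values. Outside the interaction these genes had been picked for arrays that did not overlap, which all but fixes their sign, so this is no sign of robustness. Of all 2442 gene values 53 lost and 20 gained a call, 79 moved by more than their error with no call, 2290 did none of these and 0 called values reversed. The 82 values with the other sign belonged to serotonin genes that passed in no setting. Of the list values, where only arrays of the groups compared were left out singly, 2211 stayed on their side of the threshold, 10 lost and 11 gained a call; arrays of other groups ended the cerebellum call in 2 more cases. The estrogen count was 0 in every setting.

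Probe sets past the threshold moved as follows, and the cause was not tested beyond what each setting changes. For progesterone (3 in the fit as reported) there was 1 with the values as deposited, 5 with no filter, 1 with the lowest 60% left out, 6 with array weights, 0 with only the groups compared, 11 without the 2 arrays of high ribosomal signal, and 0 to 3 with single arrays left out. For both hormones (1) these gave 2, 0, 0, 2, 0, 0 and 0 to 1 in the same order. For both against estrogen (0) the range with single arrays left out was 0 to 2. For both against progesterone (1) there were 6 with no filter, 0 with the lowest 60% left out, 0 with the offset of the 25th percentile, 2 with variance trend and robust fitting, 12 with array weights, 3 with only the groups compared and 0 to 1 with single arrays left out. For the interaction (0) there was 1 with no filter, 2 with array weights and 0 to 1 with single arrays left out. For the mean of all hormone groups (1) there were 0 with no filter, the lowest 60% left out, the 25th percentile offset, variance trend and robust fitting, or the 2 arrays left out, 2 with array weights and 0 to 1 with single arrays left out. For the F test (4) there were 2 as deposited, 0 with a common median, 0 with the lowest 60% left out, 0 with the 25th percentile offset, 2 with variance trend and robust fitting, 10 with array weights, 2 without the 2 arrays and 0 to 4 with single arrays left out. Without the 2 arrays the counts at an unadjusted p under 0.05 were 869 for progesterone, 310 for both hormones and 681 for the F test (436); with array weights they were 963 for progesterone (621), 1009 for both against progesterone (581), 654 for the interaction (376) and 947 for the F test. The estrogen and both-hormones correlation was 0.511 with no filter, where the highest simulated value was 0.535. Where leaving out an array left 2 in a group, the shared spread was used. Low signal limits the dimmest probe sets, such as that of PGR, whose intensities lay under the offset. Low readings also enter the calls of LPCAT4 (15.9 to 21.7 on the progesterone arrays) and DMAC2L (16.7 to 22.6 on the placebo arrays). Both lay under the 25th percentile of all values (23.8). With the lowest 60% left out, the called probe sets of LPCAT4, UBXN7 and DMAC2L were not tested, so their ranges do not hold that setting.

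With the replicate number as a block, the count was 0 for progesterone, 0 for both against progesterone and 0 for the F test, and the block moved no other count of probe sets past the threshold. The cerebellum list with estrogen had an adjusted p of 0.0644 under the block. Of 18 pairs with the same number 5 had a correlation over 0.1 (from −0.216 to 0.407), 3 of them between estrogen and estrogen plus progesterone, the only 2 groups whose pairs all did, and 5 of 12 arrays correlated best with their own number. The 3 pairs of 2 groups are not separate signs, since deviations from a group mean cancel out within the group. For those 2 groups the block changed no call, and the fit of their 6 arrays with the block called 0.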

Other observations

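The hormone averages, their regroupings and the correlations in this part were all chosen after the data were seen.

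ADGRE5, the adhesion receptor CD97, separated the arrays by estrogen whether or not progesterone was present. Its intensity lay between 69.9 and 93.9 with estrogen and between 86.6 and 98.9 with both hormones, against 23.6 to 35.3 with placebo and 29.2 to 41.9 with progesterone (n = 3 each). Averaged over progesterone, with 6 arrays on each side, the log2 change with estrogen was 1.18 ± 0.14 (SE, limma adjusted p = 0.0174), higher on 6 of 6 arrays, and ADGRE5 was the 1 probe set called. Regroupings did not exclude chance for that count, since 9 of 100 gave at least 1 and the highest other gave 4. The fit and its regroupings took the 6 arrays with estrogen as independent. Same-numbered estrogen and estrogen plus progesterone arrays deviated together (correlations of 0.407, 0.296 and 0.133), and no paired fit was run for this average. The next genes by p did not pass: LPCAT4 at 1.11, DDX17 at 0.55, the metalloproteinase inhibitor TIMP1 at −1.25, DMAC2L at 0.95 and BTRC at −0.83 (adjusted p = 0.340). The genes named here were picked by their p in this added comparison.

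Averaged over estrogen, progesterone gave 0 calls by limma, with 440 probe sets at an unadjusted p under 0.05 where 376.75 are counted with no effect. All 100 regroupings reach a count of 0 of necessity, which tests nothing, and the highest other gave 2. The genes with the smallest p were DMAC2L at 1.23 (adjusted p = 0.194), HOXB3 at −0.88, LPCAT4 at −1.04 and PDYN at −1.22 (adjusted p = 0.390). PDYN read 91.4 ± 34.3 with placebo, 75.7 ± 19.0 with estrogen, 41.9 ± 19.0 with progesterone and 22.9 ± 1.9 with both hormones (SD, n = 3).

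Changes measured on separate arrays can be set against each other without shared controls, although separate arrays need not be independent. Across probe sets, which are not independent replicates, the change with progesterone against placebo had a correlation of −0.0097 with the change from estrogen to both hormones (2-sided exact permutation p = 0.86 over 400 relabellings, of which the highest gave 0.135). For estrogen against placebo and progesterone to both hormones it was 0.022 (p = 0.92 by the same exact permutation test, highest 0.328). Of the 621 probe sets at an unadjusted p under 0.05 with progesterone, 56.0% had the same sign in the other pair, and of the 238 with estrogen, 58.0%. These correlations were set aside as tests of a hormone effect after their values were seen, because a few responding genes would be diluted among 7535 probe sets. That reason does not cover the shares of the same sign, which were taken only among probe sets at an unadjusted p under 0.05. Those shares had no permutation reference. Same-numbered estrogen and estrogen plus progesterone arrays deviated together, which can raise the share for estrogen with no hormone effect.

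On component 3, which held 12.7% of the variance, placebo 1 (15.5), progesterone 2 (25.2) and progesterone 3 (16.4) lay apart from the other arrays.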
